A study of Drosophila melanogaster with 8 samples.

How the data were processed

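Total RNA from 5 pooled whole wandering larvae of the last larval instar per library was depleted of ribosomal RNA with a kit made for human, mouse and rat, and sequenced on an Illumina HiSeq instrument as 50 bp paired reads, with 8 libraries in a lane and each library run over 2 lanes. There were 4 genotypes with 2 libraries each: WT (Oregon R+), hsromega66, Hsp90GFP and larvae labelled as the Hsp90GFP hsromega66 recombinant. The labels put the 3 mutant genotypes in another background (w1118; Sp/CyO') than WT, so every comparison against WT also compares backgrounds.

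The submitters' processing notes name TopHat, Bowtie, Cufflinks and Cuffdiff 2.1.1 and the genome build dm6; versions of TopHat, Bowtie and Cufflinks are not given in the sources used here. The deposited tables compare each pair of the 4 groups, in 6 tables of 15904 rows. Per the file headers, the group values are FPKM (fragments per kilobase of gene, scaled to the mapped fragments), 1 value per group. The deposited test statistic of Cuffdiff is a score, and it was used with the fold to obtain a standard error. The deposited p-value and q-value of each row are the authors' own, with a smallest p-value of 5e-05. The deposited tables' column of log2 folds was not used, because cells with a group at 0 hold no number; folds were recomputed from the FPKM.

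The tables hold 1 value per group and gene, so calls rest on the authors' test: a gene was called when its deposited q-value was under 0.05 and its test status was OK. These calls were the same as the authors' own flag in all 6 tables. The largest p-value called was 0.00395, for which the deposited q-value was under 0.05, while a Benjamini-Hochberg adjustment over the 75427 tests in the 6 tables gives 0.0913; the set of tests behind the deposited q-values is not given in the sources used here. Log2 folds were taken as log2(FPKM + 1), which understates folds of genes at low levels, and were used to rank genes; printed folds are ratios of FPKM, and a group listed at 0 gets no fold. The standard error of each log2 ratio was taken as the ratio divided by the deposited statistic, with a median of 0.997 to 1.03 by comparison. Intervals of ratios in the closing section are 95% normal intervals from that error.

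Non-additive change was tested as the log2 ratio of the libraries labelled as the recombinant to Hsp90GFP minus that of hsromega66 to WT, with a z test on the summed squared errors and Benjamini-Hochberg adjustment over 11657 genes; 170 genes tested in all 6 tables were left out because a group was listed at 0. Overlaps of calls were set against independent lists and against 200 simulations with no effect that drew the WT values once per gene for all comparisons set side by side. The 33 gene lists were written before the data were examined. They held 729 members, of which 667 had a row of their own, 41 were in rows merged with other genes and 21 were not matched. Each list was tested in each direction and comparison with Fisher's exact test, two-sided, against the other tested genes, with Benjamini-Hochberg adjustment over 396 tests. Counts adjusted over the list alone take the deposited p-values of the members only. The median log2 fold of each list was ranked among 10000 random lists of the same size, matched on expression in 20 bins. The random lists drew genes independently. Members of a list can vary together between pools of larvae, so the rank does not measure the spread between pools.

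Genes were named by a rule fixed before the data were examined. It took hsromega, Hsp83, white and l(2)gl; the 8 highest and 8 lowest log2 folds per comparison among called genes of at least 5 FPKM in either group that are named protein-coding or CG genes; up to 4 called members of each list with an adjusted p under 0.05 or with at least 3 called members; and the 5 largest non-additive values in each direction. Other genes named were chosen after their values were seen: Lsp1alpha, Lsp1beta, Dpt, Dro, IM3, IM14, Mhc, Hrb87F, Hsp23, Hsp70Ba, ebony, roX1, roX2, Sgs3, Sgs8, dlg1, scrib, Ice, Damm, TotC, spok, MtnB, betaTry, ninaD and Amy-d where they stand outside the rule, and the neighbours of l(2)gl.

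Symbols were looked up in the Ensembl release 115 annotation (BDGP6.54, Release 6, the assembly of dm6): of 15113 single symbols, 11217 were current and 15015 (99.4%) were current or older ones. Rows that merge several genes (637) and the 74 symbols found on several rows were kept in the counts but not named by rule. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The tests were checked on simulated data. The comparison with WT was called there by a z test on the implied standard errors, so the recovery of the deposited q-value was not measured. With 200 of 11752 genes changed in 20 draws, a log2 change of 4 was recovered in 53.1% of genes with 4.47% false calls in the comparison of the libraries labelled as the recombinant with WT, and in 23.3% with 4.84% false calls by the non-additive test; for a log2 change of 2 the shares were 7.5% and 2.1%.

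The alternatives tried were a q under 0.01, a minimum of 2-fold, a minimum of 1 FPKM, leaving out non-coding and merged rows, median-centred folds, another pseudocount (0.1 FPKM), another path through the tables for the non-additive test, and 4 choices added after the data were seen. Depth per library was not analysed here, and leaving out a replicate could not be run without values per library. The reads themselves were not used here.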

Results

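RNA was sequenced from whole wandering larvae of the last larval instar of 4 genotypes: wild type (WT, the Oregon R+ strain), hsromega66, Hsp90GFP, and larvae labelled as carrying Hsp90GFP and hsromega66 together on a recombinant chromosome. hsromega66 is a near-null allele of hsromega, a long non-coding RNA that organises nuclear omega speckles. Hsp90GFP over-expresses Hsp83, the fly Hsp90 chaperone. Each genotype had 2 libraries of 5 pooled larvae, so 8 libraries in all. The authors' value is 1 FPKM per gene and group, pooled over both libraries, and no value per library was used here, so no spread between replicates stands beside any level. The read depth per library is unknown from these tables. The authors' group FPKM summed to 938839 in WT, 1043230 in hsromega66, 893055 in Hsp90GFP and 1202780 in the libraries labelled as the recombinant. At least 1 FPKM was listed for 11159 genes in WT, 11097 in hsromega66 and 11176 in Hsp90GFP, against 9931 in the libraries labelled as the recombinant, where 2067 genes were listed at 0 (WT 1303). A gene is called below when its q in the authors' deposited table was under 0.05, and the called q values ran from 0.00144 to 0.0497 in the authors' deposited table. Folds are ratios of the authors' group FPKM.

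The first question was whether each genotype showed its named change. Hsromega (FBgn0001234, dm6 3R 21296127 to 21317836, plus strand, 8 distinct exons) was at 236 FPKM in WT and 0.767 FPKM in hsromega66, a called fall of 308-fold. In the libraries labelled as the recombinant it was at 77.9 FPKM, which was 33.0% of WT and not called (q = 0.629 in the authors' deposited table), and 102-fold above hsromega66, a called rise. The level of hsromega thus lay against the label of those libraries, and they are named below as the libraries labelled as the recombinant. Hsp83 (FBgn0001233, 3L 3192969 to 3197059) was at 371 FPKM in WT, 427 in hsromega66, 1616 in Hsp90GFP and 968 in the libraries labelled as the recombinant. The ratio of 4.35 in Hsp90GFP missed the threshold (q = 0.0538 in the authors' deposited table), as did the ratio of 2.61 in the libraries labelled as the recombinant (q = 0.243 in the authors' deposited table). The eye colour gene white shares its row with CG32795, and that row was at 43.3 FPKM in WT, 26.2 in hsromega66, 26.1 in Hsp90GFP and 36.5 in the libraries labelled as the recombinant, with no call.

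**Figure D1:**
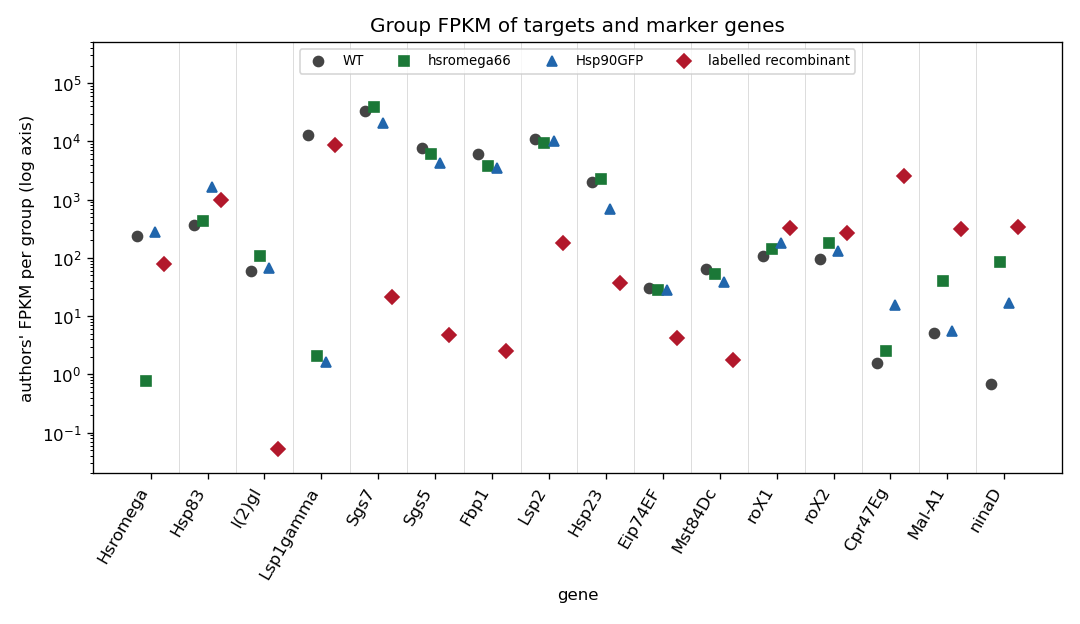
Authors' FPKM per group (vertical log axis) of 16 genes in the 4 groups, 1 point per group. Hsromega lies at 0.767 FPKM in hsromega66 and at 77.9 FPKM in the libraries labelled as the recombinant, where Sgs7, Fbp1 and Lsp2 lie at 21.2, 2.49 and 178 FPKM.

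Against WT, hsromega66 larvae had more RNA of some gut digestive enzymes and of several antimicrobial peptides. They had less of the immune-induced peptides IM1, IM2 and IM23 and of a larval serum protein. ninaD, a scavenger receptor for carotenoid uptake, rose 123-fold, from 0.682 to 84.2 FPKM. Lsp1gamma, a larval serum storage protein subunit (3L 66430 to 68995), fell 6125-fold, from 12858 to 2.099 FPKM, while Lsp1alpha (6652 and 5952 FPKM) and Lsp1beta (8845 and 7222 FPKM) were not called. Nearer the end of 3L, mthl8 was at 7.37 FPKM in WT and listed at 0 in every mutant genotype. A difference between stocks therefore cannot be told apart from an effect of hsromega66 on Lsp1gamma. Of 12523 genes tested, 155 were called, 108 higher and 47 lower, and 437 had an unadjusted p under 0.05, fewer than the 626 expected by chance. The count was 75 at q under 0.01 and 64 with a Benjamini-Hochberg adjustment of the deposited p within the table, and 31 by the implied standard errors, 22 of them among the 155.

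Among gut digestive enzymes, 8 of the 40 tested members rose and none fell (adjusted p = 7.13e-08, Fisher's exact test, two-sided), and 16 rose and 1 fell when adjusted over the list alone. Amy-d, an alpha-amylase, rose 18.7-fold, the maltase Mal-A1 rose 7.99-fold, the lysozyme LysX rose 5.88-fold and Amy-p rose 4.30-fold. The lipase Lip3, outside that list, rose 24.7-fold, and the cytochrome P450 genes Cyp4e3 and Cyp12a5 rose 37.5-fold and 3.37-fold, while Cyp12d1-d fell from 1.86 FPKM and was listed at 0 in hsromega66. Among antimicrobial and immune effectors, 6 of 29 rose (adjusted p = 4.41e-06) and 4 fell (adjusted p = 0.000109, Fisher's exact test, two-sided), and 7 rose and 5 fell when adjusted over the list alone. The attacin AttD rose 50.8-fold, Dpt rose from 25.6 to 109 FPKM and Dro from 1.65 to 28.9 FPKM. The immune-induced peptides IM2, IM23 and IM1 fell 66.5-fold, 122-fold and 17.7-fold. Their genes start close together on 2R (18386602, 18382704 and 18383949), and the exact test counts them as separate genes. Among salivary glue and late gland secretion genes, 3 of 18 fell (adjusted p = 0.000962, Fisher's exact test, two-sided) and 4 fell when adjusted over the list alone. Sgs1, a glue protein, fell 9.35-fold, Eig71Eb fell 15.0-fold, and Eig71Ed fell from 19.5 FPKM to a value listed at 0. Outside the lists, CG13560 fell 126-fold, CG16836 fell 28.5-fold, lcs fell 21.5-fold, CG7587 rose 19.2-fold, CG3397 rose 25.1-fold, CG11911 rose 14.9-fold and CG14850 rose from a value listed at 0 to 42.9 FPKM.

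None of the 19 tested muscle markers was called in hsromega66, but 18 lay below WT and their median log2 fold of -0.73 was below that of all 10000 random lists matched on expression; Mhc, muscle myosin heavy chain, was at 174 FPKM against 501 in WT. None of 23 glycolysis and sugar metabolism genes was called either, with a median log2 fold of -0.57 that also lay below all the random lists. No member of the hsromega-associated RNA-binding proteins, the proteins that sit in omega speckles, was called among 20 tested; Hrb87F was at 39.4 FPKM against 54.4, and the list's median log2 fold was -0.27, at the 0.01 percentile of the random lists. That list was also low in Hsp90GFP (-0.25, percentile 0.4), where hsromega was not reduced, and in the libraries labelled as the recombinant (-0.39, percentile 0.53). Cell cycle and imaginal disc genes were as low in hsromega66 (-0.25 and -0.31, percentiles 0.01 and 0.05), so the shift cannot be tied to the loss of hsromega. Hippo growth targets and hemocyte markers (percentiles 0.13 and 0.11) and detoxification genes (percentile 100) were extreme there too. A rank among the random lists therefore does not by itself mark a list out. The smallest change called was a log2 ratio of 1.57. In simulations of the comparison of the libraries labelled as the recombinant with WT, a log2 change of 2 was recovered in 7.5% of genes and of 4 in 53.1%. Those simulated calls came from a z test on the implied standard errors. The deposited q was not simulated, so how many changes above the smallest called size it misses is not known. By the same exact test, the glue and gut lists no longer passed when calls came from median-centred folds and their implied standard errors (adjusted p = 1.00 and 0.586), nor did the rises of the immune list at q under 0.01 (adjusted p = 0.0677).

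Against WT, Hsp90GFP larvae had less RNA of several immune-induced peptides and Lsp1gamma, and more of some glutathione transferases and digestive proteases. Lsp1gamma fell 7921-fold to 1.62 FPKM. It was also low in hsromega66 (2.099 FPKM), which has the same labelled background, so here too a stock difference cannot be told apart from an effect of the genotype. The drosomycin-like peptide gene Drsl5 fell 263-fold, from 903 to 3.43 FPKM, and IM2 fell 234-fold. CG10073 rose 279-fold, from 0.234 to 65.1 FPKM, and ninaD rose 24.7-fold. Of 12621 genes tested, 137 were called, 78 higher and 59 lower, and 386 had an unadjusted p under 0.05, fewer than the 631 expected by chance. The count was 73 at q under 0.01 and 53 with a Benjamini-Hochberg adjustment within the table, 26 higher and 27 lower, so the excess of higher calls was lost.

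Of 27 antimicrobial and immune effectors tested, 7 fell and none rose (adjusted p = 4.69e-09, Fisher's exact test, two-sided), and 8 fell and 1 rose when adjusted over the list alone. IM1 fell 71.7-fold, IM4 fell 70.6-fold and IM23 fell from 163 FPKM to a value listed at 0. IM23, IM1 and IM2 start close together on 2R (18382704, 18383949 and 18386602), and the exact test counts them as separate genes. The fall of the list thus rests in part on neighbouring genes, in a labelled background that differs from WT. Of 56 xenobiotic detoxification genes, 4 rose (adjusted p = 0.00641, Fisher's exact test, two-sided) and 1 fell, and the counts were the same when adjusted over the list alone. The glutathione transferases GstD5, GstD2 and GstE6 rose 33.5-fold, 8.52-fold and 4.65-fold, and Cyp4e3 rose 7.54-fold. Of 40 gut digestive enzymes, 4 rose (adjusted p = 0.00196, Fisher's exact test, two-sided) and 2 fell (adjusted p = 0.143), again the same counts when adjusted over the list alone. The serine proteases Jon99Fi, Jon74E and betaTry rose 6.35-fold, 5.02-fold and 4.40-fold, while LysX fell 8.91-fold. Of 18 glue and late gland genes, 2 fell (adjusted p = 0.04002, Fisher's exact test, two-sided), Eig71Eg by 11.9-fold and Eig71Ea by 11.02-fold, and 4 fell when adjusted over the list alone. The list's median log2 fold was -1.06, below all the random lists. Outside the lists, CG7924 fell 670-fold and CG34193 fell 360-fold, while CG3397 rose 31.2-fold, CG3292 rose 20.7-fold, CG13947 rose 16.1-fold, CG32284 rose 15.9-fold and the peroxiredoxin Prx2540-2 rose 15.7-fold.

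Of 21 heat shock proteins and chaperones tested in Hsp90GFP, 1 rose, Hsp70Ba, from a value listed at 0 to 0.535 FPKM, and none fell; that count was the same when adjusted over the list alone (adjusted p = 0.625, Fisher's exact test, two-sided). The small heat shock gene Hsp23 was at 702 FPKM against 1995 in WT, not called. The pigment gene ebony (symbol e, 3R 21229839 to 21237177) fell 76.2-fold. By the same exact test, the rises of the gut and detoxification lists and the fall of the glue list no longer passed when calls came from median-centred folds and their implied standard errors (adjusted p = 1.00, 0.664 and 1.00), nor did the glue and detoxification lists at q under 0.01 (adjusted p = 0.382 and 0.898). Calls made from the implied standard errors numbered 18 higher and 33 lower, or 19 and 33 with median-centred folds, so the majority of them lay on the lower side.

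The libraries labelled as the recombinant differed from WT far more widely than either single genotype. Several fat body and salivary gland genes fell: Fbp1, a storage protein receptor (3L 14094589 to 14098053), fell 2405-fold from 5996 to 2.49 FPKM, and the glue gene Sgs7 (3L 11509861 to 11510247) fell 1568-fold from 33244 to 21.2 FPKM. More cuticle protein genes rose than fell (13 and 3 of 37 tested), and Cpr47Eg rose 1577-fold from 1.58 to 2496 FPKM. The tumour suppressor and cell polarity gene l(2)gl (FBgn0002121, 2L 9839 to 21376, minus strand, 18 distinct exons) fell 1155-fold, from 59.6 to 0.0516 FPKM. Of 12656 genes tested, 1096 were called, 583 higher and 513 lower, and 2278 had an unadjusted p under 0.05. The count was 676 at q under 0.01 and 686 by the implied standard errors.

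Next to l(2)gl, the pseudogene CG11023 (2L 7529 to 9484) was listed at 0 in the libraries labelled as the recombinant, and the ionotropic receptor gene Ir21a (2L 21823 to 25155) and its antisense RNA CR43609 (2L 21952 to 24237) were at 2.12% and 2.52% of the mean of the other groups. These are low genes: in the other groups CG11023 was at 4.01 to 8.21 FPKM, CR43609 at 2.32 to 3.31 and Ir21a at 0.277 to 0.505, and of the 3 only CG11023 was called lower. l(2)gl itself was at 0.0660% of that mean. The next gene along the arm, Cda5 (2L 25402 to 65404), was at 5.84 FPKM, 96.8% of that mean.

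**Figure D2:**
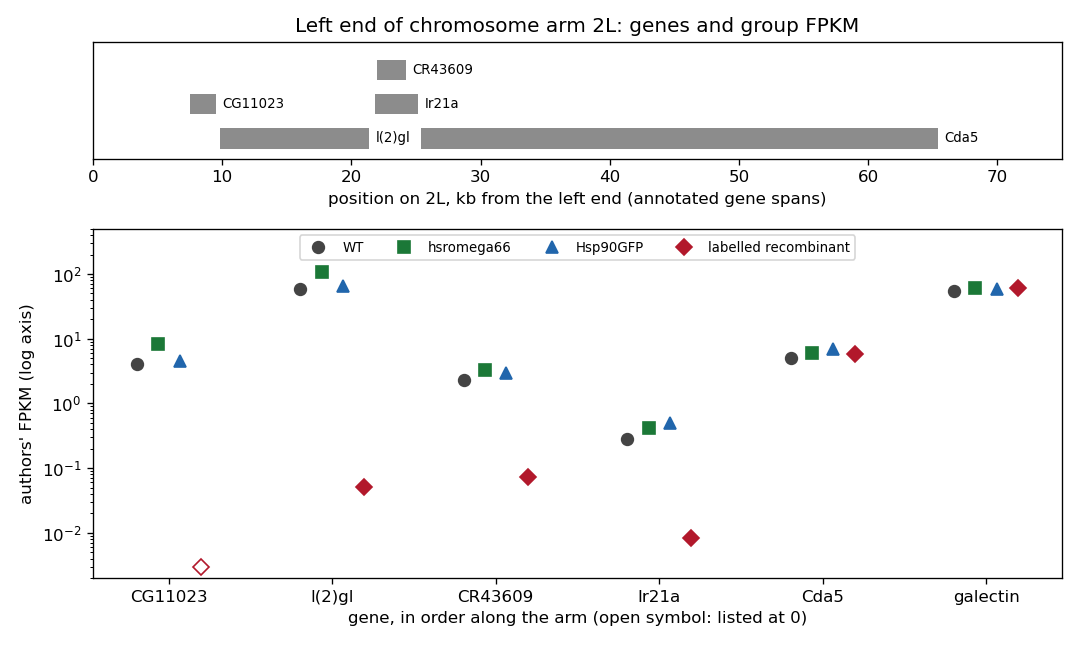
Annotated gene spans at the left end of 2L in kb (top) and the authors' FPKM per group on a log axis (bottom; open symbol, listed at 0). From CG11023 to Ir21a the libraries labelled as the recombinant lie at 0 to 2.52% of the mean of the other groups, and Cda5 lies at 96.8%.

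Among larval and pupal cuticle proteins, 13 of 37 tested members rose (adjusted p = 1.87e-07, Fisher's exact test, two-sided) and 3 fell in the libraries labelled as the recombinant, and 15 rose and 6 fell when adjusted over the list alone. Besides Cpr47Eg, Lcp65Ag1 rose 357-fold, Cpr67Fa2 rose 189-fold and Lcp65Ag2 rose 69.2-fold. Lcp65Ag3, a cuticle gene outside the list, rose 678-fold, while Cpr78E fell 843-fold. Of 40 gut digestive enzymes, 15 rose (adjusted p = 6.80e-09, Fisher's exact test, two-sided) and 1 fell, and 18 rose and 1 fell when adjusted over the list alone. The maltases Mal-A1, Mal-A7, Mal-A8 and Mal-A3 rose 62.2-fold, 47.8-fold, 19.1-fold and 15.1-fold. Of 57 xenobiotic detoxification genes, 16 rose (adjusted p = 1.47e-07, Fisher's exact test, two-sided) and 2 fell, and 24 rose and 3 fell when adjusted over the list alone. Cyp6a23 rose 33.6-fold, GstE6 23.1-fold, the glucuronosyltransferase Ugt36Bc 18.8-fold and GstE5 18.7-fold. Of 28 antimicrobial and immune effectors, 6 rose (adjusted p = 0.0201, Fisher's exact test, two-sided) and 5 fell (adjusted p = 0.0602), and 7 rose and 8 fell when adjusted over the list alone. Dro rose 109-fold, while Drsl5 fell 154-fold, IM2 fell 74.9-fold and IM23 fell from 163 FPKM to a value listed at 0.

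Of 20 heat shock proteins and chaperones tested, 6 fell and none rose (adjusted p = 0.00196, Fisher's exact test, two-sided), and 7 fell and 1 rose when adjusted over the list alone. Hsp23 (3L 9381882 to 9382765) fell 53.6-fold from 1995 to 37.2 FPKM, Hsp67Bc fell 35.9-fold, Hsp27 fell 25.0-fold and Hsp26 fell 17.5-fold. The other 14 genes were not called, and none of 12 Hsp90 co-chaperone genes was called. Hsp22 and Hsp67Bb, which share a merged row, were at 38.0 FPKM against 26.2 in WT, not called. The falls were thus those of some heat shock genes only. Of 34 testis and male-enriched markers, 7 fell and none rose (adjusted p = 0.00616, Fisher's exact test, two-sided), and 10 fell and 1 rose when adjusted over the list alone. The sperm-tail gene Mst84Dc fell 35.4-fold, S-Lap1 fell 32.0-fold, loopin-1 fell 30.6-fold and S-Lap7 fell 28.8-fold, while the dosage compensation RNAs roX1 and roX2, made in males, were at 330 and 264 FPKM against 106 and 96.5 in WT, not called. Of 20 ecdysone response genes, which follow the moulting hormone, 4 fell and none rose, with a list test that missed the threshold (adjusted p = 0.0847, Fisher's exact test, two-sided), and 8 fell when adjusted over the list alone. ImpE2 fell 308-fold, Eip78C 67.6-fold, ImpE1 11.9-fold and the ETS factor gene Eip74EF 7.06-fold. The median log2 fold of that list was -1.13, below all the random lists. Of 18 glue and late gland genes, 4 fell (adjusted p = 0.0623, Fisher's exact test, two-sided) and 9 fell when adjusted over the list alone. Sgs5 fell 1618-fold, Eig71Ee 1885-fold and Eig71Ea 7.98-fold; Sgs3 was at 0.419 FPKM against 1120.7 and Sgs8 at 1.01 against 3623, yet neither was called (q = 0.0883 and 0.374 in the authors' deposited table).

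No list test passed for fat body storage, lipid metabolism, hemocyte or juvenile hormone genes. The storage protein gene Lsp2 (3L 12129393 to 12131869) fell 61.6-fold from 10998 to 178 FPKM, Apoltp, an apolipoprotein, rose 5.58-fold, and Lsp1gamma was at 8541 FPKM against 12858 in WT, not called, nor were Lsp1alpha (5287 against 6652 FPKM) and Lsp1beta (11259 against 8845 FPKM). Of 8 larval serum and fat body storage genes, 1 rose and 2 fell (adjusted p = 0.271 for the falls, Fisher's exact test, two-sided), the same counts as when adjusted over the list alone. Of 19 lipid metabolism genes, 4 rose, among them Npc2d 10.5-fold, the acetyl-CoA carboxylase gene ACC 7.89-fold and Acsl 4.37-fold, and 1 fell, the lipid droplet gene Lsd-1, by 5.58-fold (adjusted p = 0.104 for the rises, Fisher's exact test, two-sided), with 5 and 1 when adjusted over the list alone. The lipase gene bmm fell 3.72-fold, and tobi and fbp, genes of the nutrient response, rose 33.3-fold and 3.87-fold. Of 12 hemocyte markers, 3 rose (adjusted p = 0.144, Fisher's exact test, two-sided), the prophenoloxidases PPO2 and PPO1 by 5.93-fold and 4.18-fold and the collagen gene vkg by 3.45-fold, and 4 rose and 1 fell when adjusted over the list alone. Of 11 juvenile hormone pathway genes, 3 rose (adjusted p = 0.120, Fisher's exact test, two-sided), JhI-26 by 8.19-fold, Jheh1 by 5.33-fold and Jheh3 by 4.99-fold, and the same number rose when adjusted over the list alone. The eye pigment genes v and ltd rose 4.37-fold and fell 3.96-fold, and ebony fell 46.3-fold. None of 29 proteasome subunit genes was called, yet all lay below WT, with a median log2 fold of -1.16 that was below all the random lists. Outside the lists, CG11350 rose 1429-fold, CG15515 407-fold, CG32284 255-fold and ninaD 496-fold, while CG33333, CG14332 and CG42834 fell from 429, 403 and 316 FPKM to values listed at 0.

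The apico-basal polarity list held l(2)gl as its 1 called member of 13, and its partners dlg1 and scrib were at 26.2 and 29.2 FPKM against 20.9 and 21.8 in WT, not called. Every list call against WT in these libraries held at q under 0.01 and with median-centred folds. The libraries labelled as the recombinant stood apart from the other 3 groups in some late-larval genes, testis markers and 2L-end genes at once, so no single gene group here can be assigned to hsromega or to Hsp83 alone.

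Against hsromega66, which should show the effect of Hsp90GFP in the mutant background, the libraries labelled as the recombinant again had less RNA of some glue and fat body genes and more of some cuticle genes and muscle markers. Sgs7 fell 1864-fold, Fbp1 fell 1520-fold, l(2)gl fell 2113-fold and Cpr47Eg rose 1009-fold. Lsp1gamma rose 4069-fold, from 2.099 to 8541 FPKM, and lcs rose 421-fold. Of 12488 genes tested, 912 were called, 459 higher and 453 lower, and 2041 had an unadjusted p under 0.05. Calls made from the implied standard errors numbered 171 higher and 254 lower, or 149 and 277 with median-centred folds, so that balance depended on the test, and 520 genes were called at q under 0.01. Hsp83 was at 2.27 times its hsromega66 level, not called (q = 0.379 in the authors' deposited table).

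In that comparison 5 of 19 muscle markers rose and none fell (adjusted p = 0.00788, Fisher's exact test, two-sided), and 13 rose when adjusted over the list alone. Mhc rose 8.78-fold, the troponin C gene TpnC47D 8.62-fold, the troponin T gene up 4.80-fold and the paramyosin gene Prm 4.47-fold; relative to WT, Mhc was not called, at 1531 against 501 FPKM. Of 12 hemocyte markers, 4 rose (adjusted p = 0.00997, Fisher's exact test, two-sided), the collagen genes vkg and Cg25C by 5.67-fold and 4.96-fold and PPO1 and PPO2 by 4.34-fold and 4.33-fold, and 6 rose when adjusted over the list alone. Cuticle genes rose in 13 of 39 and fell in 3, detoxification genes rose in 16 of 56 and fell in 1, gut enzymes rose in 8 of 40 and fell in 1, and immune effectors rose in 7 of 29 and fell in 3 (adjusted p of the rises = 3.62e-08, 6.80e-09, 0.00178 and 0.00156, Fisher's exact test, two-sided). When adjusted over the list alone the rises numbered 19, 21, 10 and 7. GstD7 rose 44.1-fold, Jon74E 43.1-fold, DptB 12.3-fold and AttC 11.8-fold, while Cpr49Ac fell 37.8-fold and LysX and Drsl5 each fell 107-fold. Testis markers fell in 7 of 34, heat shock genes in 5 of 20 and ecdysone response genes in 5 of 20 (adjusted p = 0.00326, 0.00889 and 0.00889, Fisher's exact test, two-sided), and 10, 6 and 7 fell when adjusted over the list alone. In the ecdysone list 1 gene rose, ImpL3, and that count was the same when adjusted over the list alone. Glue and late gland genes fell in 3 of 18 and rose in 1, and fat body storage genes fell in 2 of 8 and rose in 2 (adjusted p of the falls = 0.217 and 0.242, Fisher's exact test, two-sided), with 5 and 2 falls and 2 rises in each when adjusted over the list alone. Of the 18 glue and late gland genes, 9 lay above hsromega66, and the median log2 fold of that list was -0.23. Hsp23 fell 60.9-fold, S-Lap1 27.0-fold, Eip78C 109.7-fold and Hr4, an ecdysone-induced nuclear receptor gene, 31.9-fold. Sugar metabolism genes rose in 4 of 23, Men by 7.03-fold, ImpL3 (lactate dehydrogenase) by 4.05-fold, the glycogen synthase gene GlyS by 3.87-fold and Pfk by 3.55-fold, with a test that missed the threshold (adjusted p = 0.0980, Fisher's exact test, two-sided), and 9 rose when adjusted over the list alone. By the same exact test, the rises of immune, gut, hemocyte and muscle genes and the fall of ecdysone genes no longer passed when calls came from median-centred folds and their implied standard errors (adjusted p = 0.439, 0.664, 1.00, 1.00 and 0.119), nor did the immune, hemocyte and muscle lists at q under 0.01 (adjusted p = 0.163, 0.188 and 1.00).

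Against Hsp90GFP, which should show the effect of hsromega66 in the over-expressing background, 839 of 12605 genes tested were called in the libraries labelled as the recombinant, 443 higher and 396 lower, and 1942 had an unadjusted p under 0.05. The count was 493 at q under 0.01 and 412 by the implied standard errors, 211 higher and 201 lower, or 193 and 219 with median-centred folds, so the excess of higher calls was lost with centring. Fbp1 fell 1402-fold, Sgs7 982-fold, Sgs5 890.7-fold and l(2)gl 1276-fold, while Lsp1gamma rose 5261-fold and Cpr47Eg 161-fold. Of 18 glue and late gland genes, 3 fell and none rose (adjusted p = 0.159, Fisher's exact test, two-sided), and 5 fell when adjusted over the list alone. Yet 10 of the 18 lay above Hsp90GFP, with a median log2 fold of 0.50, so a fall of the list as a whole is not shown. Hsromega was at 77.9 FPKM against 273, not called (q = 0.506 in the authors' deposited table), so the change this comparison is named for was not detectable.

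In that comparison 9 of 26 immune effectors rose and 1 fell (adjusted p = 4.41e-06, Fisher's exact test, two-sided), and 14 rose when adjusted over the list alone. The diptericins DptB and Dpt rose 72.8-fold and 63.0-fold, Dro rose 75.1-fold and AttB rose 49.9-fold. Cuticle genes rose in 14 of 37 and fell in 3, gut enzymes rose in 14 of 40 and fell in 1, and detoxification genes rose in 16 of 56 and fell in 2 (adjusted p of the rises = 4.13e-09, 4.69e-09 and 4.69e-09, Fisher's exact test, two-sided), with 17, 20 and 19 rises when adjusted over the list alone. Cpr67Fa1 rose 193-fold, Mal-A1 57.0-fold and Cyp6a23 27.0-fold, while GstD5 fell 34.9-fold. Heat shock genes fell in 6 of 21 and testis markers in 7 of 34 (adjusted p = 0.000888 and 0.00163, Fisher's exact test, two-sided), with 8 and 10 falls when adjusted over the list alone. Hsp23 fell 18.9-fold, Hsp67Bc 10.3-fold, loopin-1 29.1-fold and S-Lap1 24.8-fold. Of 20 ecdysone response genes, 3 fell, ImpE2 152-fold, Eip78C 16.3-fold and Eip74EF 6.52-fold (adjusted p = 0.208, Fisher's exact test, two-sided), and 6 fell and 2 rose when adjusted over the list alone. Of 20 lipid metabolism genes, 3 rose, ACC 6.08-fold, Lip3 8.00-fold and Npc2d 5.15-fold (adjusted p = 0.242, Fisher's exact test, two-sided), the same number as when adjusted over the list alone.

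The single genotypes, set against each other, differed in some immune genes. In Hsp90GFP relative to hsromega66, Drsl5 fell 183-fold, AttB 18.03-fold, IM14 15.8-fold and Dpt 12.6-fold, and CG7924, CG34193 and ebony fell 404-fold, 311-fold and 131-fold. Hsromega was 357-fold higher in Hsp90GFP, a call, and Hsp83 3.78 times as high, not called (q = 0.0951 in the authors' deposited table). Of 12534 genes tested, 125 were called, 43 higher and 82 lower, and 389 had an unadjusted p under 0.05, fewer than the 627 expected by chance. The count was 79 at q under 0.01, 65 with a Benjamini-Hochberg adjustment within the table and 46 by the implied standard errors. Of 29 immune effectors, 6 fell and none rose (adjusted p = 9.88e-07, Fisher's exact test, two-sided), and 9 fell when adjusted over the list alone. Of 40 gut enzymes, 3 fell, LysX 52.4-fold, Mal-A1 7.33-fold and thetaTry 3.90-fold (adjusted p = 0.0296, Fisher's exact test, two-sided), while Jon74E rose 15.99-fold, and 7 fell and 1 rose when adjusted over the list alone. By the same exact test, that fall no longer passed at q under 0.01 (adjusted p = 0.115) or when calls came from median-centred folds and their implied standard errors (adjusted p = 0.770). CG3292 rose 166-fold, GstD5 34.1-fold, CG15534 42.3-fold, Cpr65Av 23.5-fold and CG14957 18.9-fold, and CG32581 rose from a value listed at 0 to 12.2 FPKM. CG9822, CG7906 and CG43166 fell 103-fold, 41.6-fold and 23.7-fold. Muscle markers, none of them called among 19, had a median log2 fold of 1.08, above all the random lists.

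**Figure D3:**
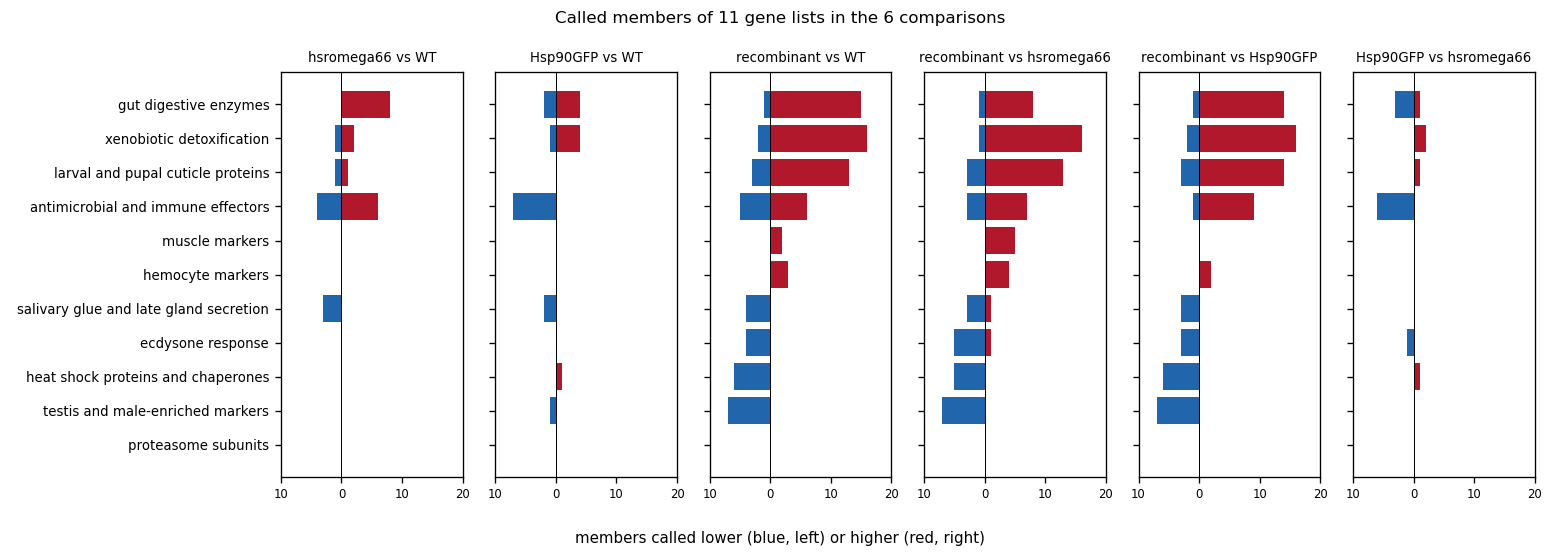
Members called lower (blue, left) and higher (red, right) in 11 of the gene lists, in each of the 6 comparisons, as numbers of genes. Cuticle proteins reach 13, 13 and 14 called higher in the 3 comparisons of the libraries labelled as the recombinant, and heat shock genes 6, 5 and 6 called lower.

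The libraries labelled as the recombinant can depart from the sum of the differences seen in the single genotypes. Such a departure is a response to the combination only if these libraries carry both changes. The hsromega level, 77.9 FPKM against 0.767 in hsromega66, does not show that, and differences between stocks could give the same result. By a z test of the difference of differences, 56 of 11657 genes were called at an adjusted p under 0.05, 18 higher and 38 lower than the sum, and 597 had an unadjusted p under 0.05. Lsp1gamma had the largest positive value, 24.94 on the log2 scale (SE 1.84), since it was near 0 in both single genotypes and near its WT level in the libraries labelled as the recombinant. lcs, the cuticle gene Cpr67Fa1, IM4 and CG40198 followed with 10.98, 9.44, 8.49 and 8.34. CG7587 had the lowest value, -13.13, with 145 FPKM in WT, 2783 in hsromega66, 223 in Hsp90GFP and 0.477 in the libraries labelled as the recombinant. CG31698, CG15404, Sgs8, CG42460 and l(2)gl followed with -12.38, -11.81, -11.65, -11.57 and -11.19. Neither Hsromega, with 6.46, nor Hsp83, with -0.94, was called. Of the 56 genes, 32 were also called against WT. CG15404, CG31698, CG42460 and Sgs8 were not among those, since this test takes the standard error implied by the deposited statistic and not the deposited p.

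The 3 comparisons against WT shared calls in the same direction. The labels put the 3 mutant genotypes in a background (w1118; Sp/CyO') that differs from WT. Shared calls may thus be strain differences, which simulations that hold only the WT values in common do not cover. hsromega66 and Hsp90GFP shared 45 genes, 29 higher and 16 lower; independent lists would share 0.840, and simulations with no effect that kept the WT values in common shared 15.2 on average and 27 at most (10 and 18 for higher genes, 5.17 and 11 for lower). hsromega66 and the libraries labelled as the recombinant shared 101 genes, against 6.77 for independent lists and 53.0 on average and 67 at most in the simulations. Of these, 84 were higher (simulated 35.6 on average, 46 at most) and 17 lower (17.3 and 26), so the sharing of lower genes lay within the simulated range. Hsp90GFP and the libraries labelled as the recombinant shared 88 genes, against 5.76, 48.1 and 60, with 56 higher (38 at most in the simulations) and 32 lower (32 at most), so here too the lower genes did not exceed the simulated range. At q under 0.01 the overlaps were 21, 45 and 47 genes. All 3 comparisons shared 34 genes, against 8.88 on average and 18 at most in simulations with no effect. Of these, 22 were higher (5.79 and 12), among them ninaD, betaTry, Amy-d and the metallothionein MtnB, and 12 lower (3.10 and 10), among them IM2, IM3 and IM23. IM23, IM2, IM3 and CG16836 all start between 18382704 and 18388995 on 2R, so the shared lower genes are not all separate loci. The simulations left out genes at 0 in a group they compared, while the observed overlaps counted them. Among the shared lower genes, IM23, CheB38a, Cyp12d1-d, mthl8 and CG43149 had such groups, as did CG12766 and CG14850 among the higher. An excess of shared lower genes is therefore not shown, here or for hsromega66 and Hsp90GFP.

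Over the 33 gene lists, 31 of 396 tests had an adjusted p under 0.05. The 23 lists with no such test were the Hippo growth targets, Hsp90 co-chaperones, JNK pathway, Notch pathway, Ras and EGFR pathway, Turandot and JAK-STAT, apico-basal polarity, apoptosis and caspases, cell cycle and replication, ecdysone synthesis and turnover, eye pigment and background markers, germline and early ovary markers, glycolysis and sugar metabolism, hsromega and Hsp83 targets, hsromega-associated RNA-binding proteins, imaginal disc patterning, insulin and nutrient response, juvenile hormone pathway, larval serum and fat body storage, lipid metabolism, neuroblast and neural markers, proteasome subunits and replication-dependent histones. Among caspase genes, Ice fell from 58.7 FPKM in WT to 15.5 FPKM in the libraries labelled as the recombinant and Damm rose from 6.80 to 25.3 FPKM. The Turandot stress gene TotC rose from 7.41 to 88.3 FPKM there, and the ecdysone synthesis gene spok fell from 15.5 to 1.42 FPKM.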

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

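All tests of explanations in this part were chosen only after the results were seen; the test of non-additive change itself was set before the data were examined. A difference of differences between the genotypes marked 56 genes, and the following values are on the log2 scale. Among those above the sum of the single genotypes, Lsp1gamma had 24.94, lcs 10.98, Cpr67Fa1 9.44, IM4 8.49 and CG40198 8.34. Lsp1gamma and IM4 were not above WT in the libraries labelled as the recombinant (8541 against 12858 FPKM and 133 against 485 FPKM). Their values reflect low levels in hsromega66 (2.099 and 26.2 FPKM) and Hsp90GFP (1.62 and 6.87 FPKM). Among those below the sum, CG7587 had -13.13, CG31698 -12.38, CG15404 -11.81, Sgs8 -11.65, CG42460 -11.57 and l(2)gl -11.19.

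l(2)gl was at 0.0516 FPKM in the libraries labelled as the recombinant and at 59.6 to 109 FPKM in the other 3 groups. A change of l(2)gl transcription alone is argued against, because its 3 neighbours were low with it, the highest at 2.52% of the other groups. These are low genes, and of them CG11023 (4.01 to 8.21 FPKM in the other groups) was called lower, while CR43609 (2.32 to 3.31) and Ir21a (0.277 to 0.505) were not. Ir21a and its antisense RNA CR43609 overlap, so they are not separate neighbours, and the argument rests mainly on CG11023. Lower detection in these libraries is argued against too, because only 0.781% of 4481 genes at 10 to 200 FPKM in WT (35 genes) lay under 1% of their WT value. Loss of the end of 2L, short of Cda5, is a candidate explanation: all 4 genes at the end were under 5% of the other groups, and 0.825% of 2544 windows of as many genes elsewhere on the arm (21 windows) were as low. The run was picked because its genes were low, so that share shows how rare such runs were and is no separate test. No reads were used here to look for a break, and a silenced chromosome end was not tested, so either may account for the pattern.

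hsromega was at 77.9 FPKM in the libraries labelled as the recombinant and at 0.767 FPKM in hsromega66. Larvae like those of the WT libraries among the pooled larvae are argued against, because 44 of 663 genes of at least 100 FPKM in WT lay at less than 1/5 of the share of WT that hsromega had. By the same test larvae like those of the Hsp90GFP libraries are argued against, with 24 of 676 genes. Both tests cover only larvae at the developmental time of those libraries. Larvae of either genotype at another time, a candidate below for the low glue and fat body genes, could fail them too and were not tested. An hsromega66 allele that was not homozygous in the pools cannot be told apart from one that was mislabelled or from homozygous larvae with raised expression, because the 95% interval of the ratio to WT, 0.0254 to 4.29, is too wide. The ebony gene, near hsromega on 3R, was at 0.925 FPKM there, at 0.562 FPKM in Hsp90GFP and at 73.3 FPKM in hsromega66, which may point to the source of that part of the chromosome but was not tested.

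The glue genes Sgs5 and Sgs7, the fat body genes Fbp1 and Lsp2 and the testis list were low together in the libraries labelled as the recombinant. Fewer male larvae in the pools is argued against, because the male RNAs roX1 and roX2 had lower 95% bounds of 0.851 and 0.865 times WT, while the testis list lay at a median of 0.0534 times WT. Less salivary gland RNA would leave the testis list alone, yet 7 of its 34 genes were called lower than in WT. Those values argue against it as the sole cause of the joint fall. For the glue genes by themselves it cannot be told apart from other causes. The fat body storage list, which it would also leave alone, had a median log2 fold of -0.070 but 2 of 8 genes called lower, Fbp1 and Lsp2. Larvae at another developmental time than the WT larvae is a candidate. The called members of the ecdysone response list against WT (4 of 20) were all lower, and the list's median log2 fold was -1.13. Its test missed the threshold (adjusted p = 0.0847, Fisher's exact test, two-sided). Against hsromega66 5 were lower and 1 higher. By the same exact test, that fall no longer passed with median-centred folds and their implied standard errors (adjusted p = 0.119). Whether such a shift would come from the genotype, from the loss of l(2)gl or from the choice of larvae stays open, since the design holds no second time point and no other group low in l(2)gl.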

How the results depend on the processing

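No paired analysis was possible because the tables hold 1 value per group, and for the same reason neither leaving out a replicate nor a replicate block could be run; the read depth, which would limit low genes, is unknown. In the order hsromega66, Hsp90GFP and the libraries labelled as the recombinant against WT, those libraries against hsromega66 and against Hsp90GFP, and Hsp90GFP against hsromega66, the called genes numbered 75, 73, 676, 520, 493 and 79 at q under 0.01. They numbered 32, 52, 697, 426, 412 and 47 with median-centred folds and their implied standard errors, and 31, 51, 686, 425, 412 and 46 without centring, so centring itself moved the counts little. In the 3 comparisons without the libraries labelled as the recombinant, Benjamini-Hochberg from the deposited p gave 62, 52 and 60 genes at 1 FPKM or more, 58, 47 and 57 without non-coding and merged genes, and 64, 53 and 65 within each table; the set of tests behind the deposited q is not known. A minimum of 2-fold could remove no call, since the smallest called log2 ratio was 1.55, and Benjamini-Hochberg over the 6 tables together left the called genes of each comparison within 1.5 times. With implied standard errors, Hsp90GFP against WT had 18 higher and 33 lower (19 and 33 centred), and the libraries labelled as the recombinant against hsromega66 had 171 and 254 (149 and 277 centred), and against Hsp90GFP 211 and 201 (193 and 219 centred); the cause was not tested. The overlaps of calls fell to 21, 45 and 47 at q under 0.01. Genes with non-additive change numbered 37 at an adjusted p under 0.01 and 101 with p read from the deposited relation of statistic to p, and the 11 named kept their call under every alternative. The other path for this test forms the same difference with the same summed errors, so its 56 genes were fixed in advance. All these alternatives use the same implied standard errors, so the kept calls do not test those errors. Of 31 list calls, 19 kept theirs under every alternative, 7 were lost at q under 0.01 and 11 with median-centred folds and their implied standard errors. That alternative changed the test as well as the centring, and no uncentred one was run for the lists. Of the 265 named log2 folds, 36 moved by more than their error with a pseudocount of 0.1 and 14 with centring. The adjustments within and over the tables, the uncentred test and the deposited relation of statistic to p were chosen after seeing the data.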

Other observations

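The groups of genes in this part were chosen after their values were seen. Family members such as Mal-A1, Ugt36Bc, Cyp6a23, GstE6 and Cpr47Eg were also in the gene lists above, so the family tests partly repeat those results. By symbol family, 7 of 10 maltase-related genes (Mal), 7 of 15 glucuronosyltransferases (Ugt) and 14 of 75 cytochrome P450 genes (Cyp) were called higher in the libraries labelled as the recombinant than in WT (adjusted p = 3.21e-05, 0.000394 and 0.00145, Fisher's exact test, two-sided, over 760 tests of 65 families). Cuticle genes of the Cpr family went both ways, with 11 of 45 called higher and 8 lower (adjusted p = 0.000985 and 0.0144, Fisher's exact test, two-sided). In Hsp90GFP against WT, 4 of 34 glutathione transferases (Gst) were called higher (adjusted p = 0.00397, Fisher's exact test, two-sided). The 34 genes called the same way in all 3 comparisons against WT included CG32284, at 10.3 FPKM in WT, 126 in hsromega66, 164 in Hsp90GFP and 2622 in the libraries labelled as the recombinant, CG15829 at 64.1, 321, 599 and 3063 FPKM, MtnB at 19.3, 160, 116 and 181 FPKM, and the chitinase gene Cht4 at 1.11, 10.8, 14.4 and 41.9 FPKM.

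At the left end of 3L, mthl8 (22428 to 26308) was at 7.37 FPKM in WT and listed at 0 in the other 3 groups, while Lsp1gamma, farther in, was at 12858 FPKM in WT, 2.099 in hsromega66, 1.62 in Hsp90GFP and 8541 in the libraries labelled as the recombinant. CG43149, between them, was at 0.815 FPKM in WT and listed at 0 in the other groups. Beside Lsp1gamma, CR44510 was at 1.45, 0.0561, 0 and 0.910 FPKM in the same order of groups. Apart from Lsp1gamma these are low rows, and a loss of this chromosome end in some stocks was not tested. CR41602 (X 23211192 to 23213166), annotated as an 18S ribosomal RNA pseudogene, was listed at 0 in WT and Hsp90GFP, at 11999 FPKM in hsromega66 and at 22248 FPKM in the libraries labelled as the recombinant. That row was not called in any comparison. The merged row of let-7, let-7-C, mir-100 and mir-125 was at 67.9 FPKM in WT, 13.1 in hsromega66, 98.0 in Hsp90GFP and 0.0183 in the libraries labelled as the recombinant, not called in any comparison. By chromosome arm, 8.63% of tested genes on 2L, 9.21% on 2R, 8.79% on 3L, 9.98% on 3R and 6.02% on X were called in those libraries against WT.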
